A study of Homo sapiens with 6 samples.

How the data were processed

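RNA of HL-60 cells was sequenced in 6 libraries, 3 labelled control and 3 of cells given 10 uM amiodarone for 24 h, per the labels. Total RNA was extracted with a phenol reagent and made into libraries with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name fastp 0.23.4, STAR 2.5.3a, featureCounts and GRCh38.p12, without their roles or order. Whether counting used strand, how reads that fit several genes were treated and which annotation was used are not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical copies, are therefore uncertain, and for genes named by the rule below, overlaps of more than 15% of the exonic bases are given with the gene.

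The deposited table holds 1 row per gene, 17911 in all and each of the type mRNA, with an Entrez gene ID, a symbol, an Ensembl ID and 6 columns headed as expression, 1 per library. The unit is not stated per the file headers. The deposited values behave like RPKM, reads per kilobase of gene and per unit of sequencing depth. They are not whole numbers, and their sums differ between libraries (534486 to 574483). Value times gene length, summed over genes, comes to 1.23 to 1.26 times the total that RPKM over the same lengths would give. Low values of short genes tend to fall near multiples of a step that depends on gene length. Of these low values, 53.6% to 63.0% lay within 0.15 of a whole step, where chance gives 30% for a step fixed in advance; the step was instead chosen to raise this share. The step put the depth at 17400000, 17600000 and 18400000 reads or fragments in the controls and 16000000, 16800000 and 15600000 in the amiodarone libraries. At that depth a value of 1 stands for about 52 to 61 reads in a gene of the median length of 3.33 kb. Whole reads could not be recovered, and the depth is an estimate that every statement on counting noise rests on. Replicate spread was above it: over 5924 genes with a value of at least 10, the median coefficient of variation was 2.73% in controls and 3.24% after amiodarone, where counting alone would give 2.57% and 2.81%. Medians over 3 libraries run low, and with allowance for this the variance was 1.62 times that of counting in controls and 1.92 times after amiodarone. No pair of libraries was a duplicate, since at most 0.63% of genes had identical values in 2 libraries.

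26 symbols that a spreadsheet had turned into dates were restored through their Entrez gene IDs. Coordinates and exon overlaps were taken from GENCODE 29 (GRCh38) by Ensembl ID for 17187 rows, and current symbols and gene types from a RefSeq gene table by Entrez ID for 17640 rows. The table has no row for a mitochondrially encoded gene.

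The design, like the gene lists and the rule for named genes, was fixed before the data were examined. It assumed counts and a quasi-likelihood count model, and named limma for the case of a normalized unit. Since the file held another unit than the design assumed, the second was used. Values were used as deposited, without further scaling; 11445 genes with a value of at least 1 in at least 3 libraries were tested, and 6466 were not. The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend) on log2(value + 1), with no covariate, 4 residual and 6.59 prior degrees of freedom, and Benjamini-Hochberg adjustment over all tested genes. Fold changes in log2 are on this scale, which understates the change of low genes. Counts of genes by size of change, such as those of at least 2-fold or under 1.25-fold, are on it too. The folds given for single genes are ratios of group means of the deposited values. Means are given ± SD over 3 libraries.

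Of 38 gene lists, the 31 with at least 5 tested members were tested with camera at a preset correlation of 0.01 and adjusted over these 31, with camera at an estimated correlation and with fry as alternatives. Camera compares a list with the other genes, and fry tests whether a list's genes move, on balance, in 1 direction. With an estimated correlation camera also tests on the 4 residual degrees of freedom, which by itself raises p. Some genes are in several lists, and lists are not independent of each other. Shares of summed values were compared with an exact permutation test of the difference of means. Named genes follow a rule fixed in advance: SIRT3; the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes with no overlap between groups, a mean of at least 5 in the higher group and a name that is not that of a clone, pseudogene or antisense gene; up to 4 members with the smallest adjusted p of each list, or 2 by level where none was called; and SQSTM1, MAP1LC3B, TFEB, PINK1, BNIP3, SOD2 and HMGCS1. Some genes that the rule would name are not reported here. Genes named outside this rule are said to be so.

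The procedure was tested on 10 simulated data sets of 11445 genes with the real means and fitted variances, for amiodarone against control. Of 50 genes changed by each size, it called 67.6% at a log2 change of 0.25, 98% at 0.5, and 100% at 1 and at 2. The changed genes all had a control mean over 2 on log2(value + 1), so lower genes were not covered. 4.48% of its calls were false, against a threshold of 5%, 0.45% of lists without a change had p under 0.05, and a shifted list was found in 10 of 10 draws. Genes were drawn independently, so the share of false lists was not checked for genes that move together. Far fewer genes were changed than the 78.3% called in the data.

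Alternatives set in advance were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum value of 5, each library left out in turn, the replicate number as a block, values without the 50 most abundant genes, and for lists the other tests and members with a mean of at least 5. Added after the values were seen were scaling to equal sums, by the median of ratios and to equal upper quartiles, robust empirical Bayes variances and a limma test against a 1.5-fold change. Identity of transcripts was measured with blastn 2.17.0.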

Results

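Gene expression was measured by RNA sequencing in HL-60 cells, an established human promyelocytic leukaemia line. Cells given amiodarone were compared with controls. Amiodarone is an antiarrhythmic drug and cationic amphiphilic compound that blocks several ion channels. The 3 amiodarone libraries came from cells given 10 uM for 24 h, and the other 3 are labelled control, without saying whether they received a vehicle. The series title names amiodarone as an activator of SIRT3, a mitochondrial protein deacetylase, and names autophagic and mitophagic cell death in acute myeloid leukaemia. The comparison asks which transcripts differed between the 2 groups. The table held 17911 genes with RPKM-like values and no counts, and 11129 to 11323 genes per library had a value of 1 or more. Steps between the low values put the depth at about 15600000 to 18400000 reads or fragments per library, if the values are RPKM. Log2 values of libraries of the same group correlated at 0.9975 to 0.9982, and those of different groups at 0.959 to 0.96. The first principal component, with 93.1% of the variance, separated the groups.

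After amiodarone, most tested members of the inflammation, amino acid response, granulocyte and monocyte lists were higher. Most of the G1/S, glycolysis, heat shock and primary granule lists were lower. These lists were called with camera at the preset correlation, and those of inflammation and G1/S genes also with an estimated one. CYP17A1, a steroid 17-hydroxylase and 17,20-lyase, had the largest log2 fold change of the genes named by the rule set in advance. Its mean value rose 15.1-fold, from 2.89 ± 0.533 to 43.6 ± 1.88 (SD, n = 3 per group). The chemokine genes CCL3 (12.8 ± 0.747 to 102 ± 2.67), CXCL8 (239 ± 4.06 to 1786 ± 91.8) and CCL2 (177 ± 7.17 to 867 ± 2.07) rose. So did DDIT3, which encodes the stress transcription factor CHOP (19.4 ± 1.15 to 121 ± 0.044), and the pseudokinase gene TRIB3 (5.04-fold). IER3 rose 5.78-fold, CCDC122 6.72-fold, the interleukin-1 receptor kinase gene IRAK2 5.99-fold and FPR1, a formyl peptide receptor of phagocytes, 6.37-fold. The cytokine gene GDF15 rose from 0.057 ± 0.067 to 7.56 ± 0.18, and no fold is given because 1 of its control libraries was listed at 0. CCL3L1 rose 7.23-fold but is a near-identical copy of CCL3, so the split of reads between them is uncertain. MTRNR2L3 (7.19 ± 0.25 to 102 ± 5.86) had a larger change than CYP17A1 on log2(value + 1), 3.66 against 3.53, and a smaller ratio of means, 14.2-fold. The rule excludes pseudogene names, and gene types of the RefSeq gene table, which has the MTRNR2L genes as pseudogenes, were used to apply it. This left out other copies too, among them MTRNR2L10 (2.955) and MTRNR2L1 (2.914), with larger log2 fold changes than CCL3 (2.909). The MTRNR2L genes are described with the observations outside the lists.

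Among the named genes that fell was PRTN3, which encodes the granule protease proteinase 3 (472 ± 19.6 to 107 ± 3.01). The cell surface proteoglycan gene SDC1 (26.0 ± 0.055 to 5.90 ± 0.415), the lactoperoxidase gene LPO (9.15 ± 0.055 to 1.61 ± 0.111) and the heat shock gene HSPA6 (16.8 ± 0.28 to 3.61 ± 0.367) fell as well. TXNIP, a thioredoxin-binding protein gene, fell from 117 ± 1.47 to 31.9 ± 0.859, and PAQR4, which lies opposite PKMYT1 over 17.2% of its exonic bases, from 20.1 ± 1.22 to 4.43 ± 0.172. The other 6 were genes of DNA replication and chromatin, UHRF1, MCM4, FEN1, MCM3, PCNA and ASF1B. Each of these 24 genes, chosen by the rule, had an adjusted p of 4.47e-10 or less with limma, with no overlap between the groups.

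The limma test on log2(value + 1) called 8959 of 11445 tested genes (78.3%) at an adjusted p under 0.05, 3832 higher and 5127 lower. Most of these changes were small: 3464 called genes differed by under 1.25-fold, and 93.4% of the called genes by under 2-fold. 589 genes differed by at least 2-fold, 292 higher and 297 lower. The groups did not overlap in 9078 genes (79.3%), where chance gives 10%. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The balance of directions depends on the scaling. Of the genes past 2-fold, 49.6% were higher with the values as deposited, 61.3% after scaling by the median of ratios and 38.2% after scaling to equal sums. The number past 2-fold rose to 1129 genes at a pseudocount of 0.1, and 1352 genes passed a test against a 1.5-fold change.

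**Figure D1:**
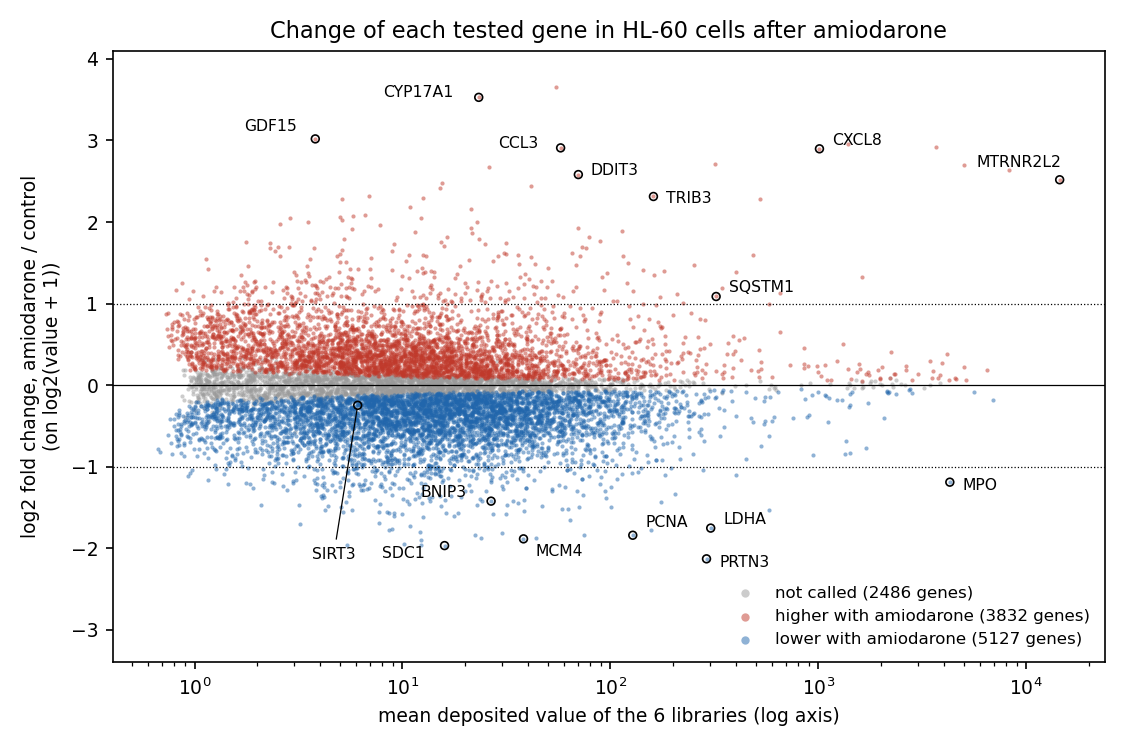
Log2 fold change of each of the 11445 tested genes (amiodarone over control, on log2(value + 1)) against its mean deposited value over the 6 libraries, on a log axis. Each point is a gene, red where higher (3832), blue where lower (5127) and grey where not called; dotted lines mark a 2-fold difference, and most called genes lie between them.

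SIRT3 transcripts were lower after amiodarone. The value fell from 6.69 ± 0.254 in controls to 5.48 ± 0.286, a log2 fold change of -0.25 with a standard error of 0.054 (limma, adjusted p = 0.00156). Each amiodarone library lay below each control library, and the groups were likewise apart in 79.3% of all tested genes. The change was under 1.25-fold on log2(value + 1), as in 3464 of the 8959 called genes, and 5127 of 11445 tested genes were called lower. SIRT3 lies on chromosome 11 at 215458 to 236931 on the minus strand (GENCODE 29, GRCh38), and 7.8% of its exonic bases overlap PSMD13 on the opposite strand. Protein level and deacetylase activity were not measured here. Of the 6 tested sirtuins, SIRT3, SIRT6 (28.0 ± 1.05 to 23.4 ± 1.65) and SIRT7 (17.2 ± 0.338 to 14.1 ± 0.452) were lower and 2 were higher, among them SIRT2 (27.9 ± 1.17 to 31.7 ± 1.24). The call of SIRT2 ended with scaling to equal sums (log2 fold change 0.092). The sirtuin list had a median log2 fold change of -0.07 and was not called (camera, adjusted p = 0.979). That median was -0.04 without control replicate 3 and turned to 0.11 without a filter on low values.

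Of 16 tested genes whose proteins are known SIRT3 substrates, 10 fell and 2 rose, with a median of -0.26 (camera, adjusted p = 0.0411). With an estimated correlation the adjusted p was 0.264. The call also ended under a minimum value of 5, without amiodarone replicate 1 (adjusted p = 0.0641), without the 50 most abundant genes and under 2 of the scalings. Transcripts of the mitochondrial enzymes IDH2 (97.4 ± 1.18 to 55.7 ± 2.01) and SDHA (35.9 ± 1.02 to 21.3 ± 0.312) and of the permeability pore regulator PPIF (103 ± 3.32 to 75.8 ± 1.77) fell. Those of the manganese superoxide dismutase SOD2 rose from 17.9 ± 0.215 to 28.9 ± 0.444, in a gene that shares 43.2% of its exonic bases with ACAT2 on the opposite strand and 33.0% with a second annotated SOD2 gene on the same strand.

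Transcripts of several autophagy genes were higher after amiodarone. SQSTM1, which encodes the autophagy receptor p62, rose 2.13-fold (206 ± 2.5 to 439 ± 4.71). WIPI1, a phosphoinositide effector of autophagosome formation, rose 3.04-fold from 4.4 ± 0.199 to 13.4 ± 0.813. The ATG8 family gene GABARAPL1 rose 2.52-fold, EPG5, a tether for autophagosome fusion, 2.24-fold, and MAP1LC3B, which encodes LC3B, 1.41-fold (11.1 ± 0.688 to 15.8 ± 0.355). In the autophagy core list 19 of 42 tested members rose, 10 fell and 13 were not called, with a median log2 fold change of 0.12 (camera, adjusted p = 0.0198). Named outside the rule, those that fell include BECN1 (53.8 ± 0.674 to 42.4 ± 0.978), ATG3 (45.4 ± 2.39 to 33.2 ± 1.85) and ATG13 (32.3 ± 0.356 to 25.9 ± 0.371). Of 17 tested genes named ATG, a grouping made after the values were seen, 5 rose and 6 fell. The autophagy list had an adjusted p of 0.108 with an estimated correlation, and a median of 0.06 with scaling to equal sums. Exons of SQSTM1 and WIPI1 overlap a coding gene on the opposite strand over 39.8% and 28.5% of their bases.

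Lysosomal genes also tended upward, with 31 of 57 higher, 16 lower and a median of 0.16 (camera, adjusted p = 0.0036). With an estimated correlation the lysosome list had an adjusted p of 0.105, and scaling to equal sums gave a median of 0.07. TFEB, a transcription factor of lysosomal genes, rose 1.92-fold (3.68 ± 0.04 to 7.08 ± 0.313). The cathepsin genes CTSD (411 ± 9.28 to 901 ± 25.3) and CTSH (1.77-fold), the acid ceramidase gene ASAH1 (1.84-fold) and GPNMB, a lysosomal membrane glycoprotein gene (3.30-fold), rose as well. Exons of CTSD overlap another annotated gene on the same strand over 54.9% of their bases. Among subunits of the V-ATPase, the proton pump that acidifies lysosomes, 11 of 17 rose and 2 fell, with a median of 0.14 (camera, adjusted p = 0.015). An estimated correlation gave that list an adjusted p of 0.182, and its median ranged over the scalings from 0.05 to 0.22. ATP6V1E1 rose 1.31-fold, ATP6V1F 1.28-fold, ATP6V1A 1.24-fold and ATP6V1B2 1.19-fold.

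Mitophagy genes moved in both directions. Of 29 tested members 12 rose, 11 fell and 6 were not called, with a median log2 fold change of 0.02, and the list was not called (camera, adjusted p = 0.345). The sign of that median is not settled, as it was -0.001 without amiodarone replicate 1, 0.005 without amiodarone replicate 2, 0.015 without control replicate 2 and -0.07 with scaling to equal sums. PINK1, the kinase that starts the PINK1 and parkin pathway, rose from 11.1 ± 0.429 to 15.8 ± 0.235. The autophagy receptor gene TAX1BP1 rose 1.64-fold, the deubiquitinase gene USP15 1.85-fold and the import subunit gene TOMM7 1.38-fold. BNIP3, a mitophagy receptor that is also a hypoxia target, fell from 39.3 ± 0.41 to 14 ± 0.417.

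**Figure D2:**
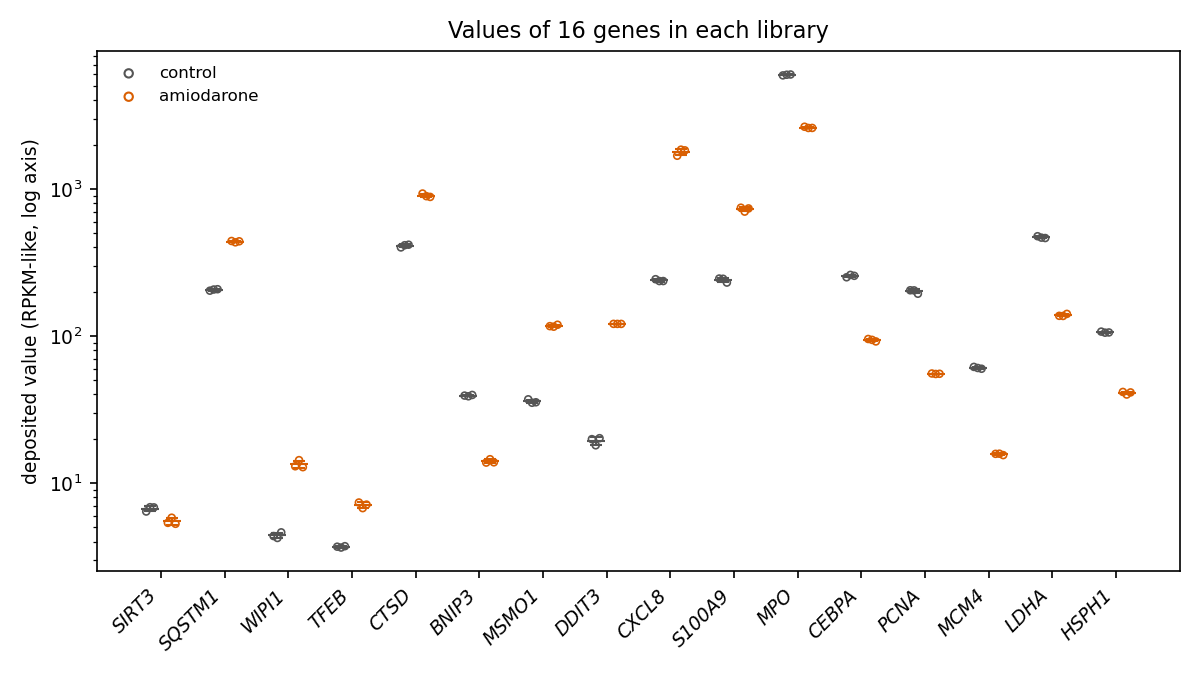
Deposited values (RPKM-like, log axis) of 16 genes in each of the 3 control libraries (grey) and 3 amiodarone libraries (orange); circles are libraries, horizontal marks the means and bars the SD. The groups are apart in each gene shown, with SQSTM1 at 206 against 439 and PCNA at 201 against 55.3.

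Genes of cholesterol synthesis and uptake were split. 16 of 26 tested members rose and 9 fell, with a median log2 fold change of 0.46 (camera, adjusted p = 0.015). Its adjusted p was 0.242 with an estimated correlation. MSMO1, a sterol methyl oxidase gene, rose 3.27-fold (35.9 ± 1.06 to 117 ± 1.86). HMGCS1 rose 1.99-fold (42.8 ± 1.08 to 85.0 ± 4.12) and CYP51A1 1.87-fold. In fatty acid synthesis 6 of 16 rose, among them ME1 (2.32-fold) and ACSS2 (1.72-fold). 8 fell, among them FASN (82.6 ± 1.37 to 41.3 ± 0.48) and SCD (124 ± 1.4 to 78.7 ± 1.16), and the list was not called (median -0.18, camera, adjusted p = 0.705). That median was -0.07 without a filter on low values and -0.30 at a minimum value of 5. A list of targets of the liver X receptors also holds the receptor genes NR1H2 and NR1H3. Of its 7 tested members 5 fell, including MYLIP (14.2 ± 0.05 to 8.72 ± 0.199), PLTP and LPCAT3, of which 66.4% of the exonic bases lie opposite EMG1. NR1H2 rose 1.18-fold, and the list was not called (median -0.40, camera, adjusted p = 0.27). The median of this list was -0.26 without control replicate 2 and -0.06 without a filter on low values.

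The amino acid and integrated stress response list was higher. 22 of 32 tested members rose and 9 fell, with a median log2 fold change of 0.41 (camera, adjusted p = 5.32e-04). Its adjusted p was 0.0735 with an estimated correlation, and its median 0.27 without a filter on low values. Beside TRIB3 and DDIT3, PPP1R15A, which encodes the phosphatase subunit GADD34, rose 3.78-fold and the amino acid transporter subunit gene SLC3A2 2.66-fold (99.0 ± 3.04 to 263 ± 2.17). Named outside the rule, the 9 that fell include PSAT1 (65.5 ± 1.18 to 41.7 ± 0.688), PHGDH (87.3 ± 0.962 to 61.3 ± 1.74) and CHAC1 (7.47 ± 0.458 to 3.74 ± 0.289). Chaperones of the endoplasmic reticulum did not move together, with 9 of 25 higher (10 adjusted over the list alone) and 13 lower. That list was not called (camera, adjusted p = 0.85), with a median of -0.08 (-0.12 without amiodarone replicate 2), a mean of 0.03 and a test in the upward direction. HSPA5, which encodes BiP, rose 1.34-fold and DNAJB9 2.41-fold, whereas the calreticulin gene CALR fell from 2141 ± 14.2 to 1251 ± 12.2. DERL3 was also lower (16.3 ± 0.61 to 5.29 ± 0.096), but 87.3% of its exonic bases lie opposite SMARCB1.

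Genes of the heat shock list fell. The list holds cytosolic chaperone genes and also HSPD1 and HSPE1 of mitochondria and SERPINH1 of the endoplasmic reticulum. 14 of 15 were lower and 1 was not called, with a median of -0.73 (camera, adjusted p = 5.55e-05). The heat shock list had an adjusted p of 0.0644 with an estimated correlation. HSPH1 fell from 106 ± 0.941 to 41.0 ± 0.883, HSP90AA1 from 584 ± 14.1 to 311 ± 3.83 and the co-chaperone gene DNAJB1 from 121 ± 1.55 to 63.0 ± 0.925. HSPA1B fell from 216 ± 1.57 to 114 ± 1.6, with reads that may be shared with its copy HSPA1A. In the antioxidant list 16 of 27 rose and 6 fell, with a median of 0.22 (camera, adjusted p = 0.0116). An estimated correlation gave the antioxidant list an adjusted p of 0.2, and scaling to equal sums a median of 0.14. NFE2L2, the transcription factor NRF2, rose 1.84-fold, and the copper and zinc superoxide dismutase gene SOD1 fell from 127 ± 1.15 to 84.0 ± 0.659. The ferritin heavy chain gene FTH1 rose 2.5-fold (931 ± 7.42 to 2328 ± 65.3), although it overlaps BEST1 on the opposite strand over 56.6% of its exonic bases.

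Genes of the cell division cycle fell together. All 38 tested G1/S genes were lower after amiodarone, 31 of them by at least 2-fold on log2(value + 1). Their median log2 fold change was -1.39 (camera, adjusted p = 3.09e-14). This call held with an estimated correlation (adjusted p = 0.0193). The replication clamp gene PCNA fell from 201 ± 6.17 to 55.3 ± 0.211 and the flap endonuclease gene FEN1 from 38.2 ± 0.431 to 9.69 ± 0.168. The helicase genes MCM4 and MCM3 fell from 60.7 ± 0.891 to 15.7 ± 0.192 and from 69.8 ± 0.754 to 18.3 ± 0.805. All 37 tested G2/M genes were lower, 11 by at least 2-fold on log2(value + 1), with a median of -0.80 (camera, adjusted p = 2.49e-10). Its adjusted p was 0.0646 with an estimated correlation. Among them were the proliferation marker MKI67 (14.1 ± 0.191 to 4.08 ± 0.091), PLK1 (43.7 ± 0.73 to 17.4 ± 0.026), CDC20 and TPX2. Of 38 genes of ribosome biogenesis and MYC targets 36 fell and 1 rose, with a median of -0.62 (camera, adjusted p = 3.35e-09). This list, too, was called with an estimated correlation (adjusted p = 0.0193). The pyrimidine synthesis gene CAD fell from 49.7 ± 0.604 to 18.0 ± 0.522, NOP56 from 164 ± 1.9 to 82.3 ± 2.37 and nucleolin, NCL, from 319 ± 2.68 to 177 ± 5.81.

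Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, went the other way. Of 6 tested, 5 rose (6 adjusted over the list alone), with a median of 0.77 (camera, adjusted p = 0.0116). The histone list had an adjusted p of 0.213 with an estimated correlation. Of its 27 members in the table most were under the filter, and without a filter the median was 0.32. Some tested members passed the filter only through the amiodarone libraries, which favours a rise. Of 19 alternatives for lists, 14 could be run here. Too few members were left without any 1 amiodarone library, at a minimum value of 5 or with members of a mean of at least 5. Values were low, at 8.66 ± 0.408 and 17.5 ± 2.12 for HIST1H1C and 4.45 ± 1.18 and 8.94 ± 1.16 for HIST1H2AC. Genes of cytosolic ribosomal proteins differed little, with 27 of 59 higher, 13 lower and a median of 0.05 (camera, adjusted p = 0.0198). An estimated correlation gave the ribosomal list an adjusted p of 0.537. The median was 0.03 without amiodarone replicate 1 and turned to -0.04 when libraries were scaled to equal sums, and the call also ended without a filter on low values. RPS15 rose 1.19-fold, RPL27 1.23-fold, RPL37 1.19-fold and RPL31 1.17-fold.

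Among myeloid genes, those of primary granules and progenitors were lower and those of mature granulocytes and monocytes higher. In the first list 12 of 16 fell and 4 rose, with a median log2 fold change of -0.92 (camera, adjusted p = 0.0075). Its adjusted p was 0.105 with an estimated correlation, and its median -0.59 without a filter on low values. The myeloperoxidase gene MPO fell from 5962 ± 43.7 to 2613 ± 28.4, the transcription factor gene CEBPA from 256 ± 4.82 to 93.7 ± 1.81 and MS4A3 from 262 ± 8.49 to 129 ± 4.08. In the granulocyte maturation list 14 of 19 rose, 11 of them by at least 2-fold, and 4 fell, with a median of 1.2 (camera, adjusted p = 2.45e-05). The granulocyte list had an adjusted p of 0.108 with an estimated correlation. Of its 28 members in the table the rest were under the filter, and without a filter the median was 0.34, still called. A gene can pass the filter through the amiodarone libraries alone, which favours a rise. The calprotectin genes S100A9 (240 ± 8.47 to 728 ± 23.6) and S100A8 (56.6 ± 1.65 to 172 ± 5.35) rose.

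In the monocyte and macrophage list 9 of 10 tested members rose and none fell, with a median of 0.65 (camera, adjusted p = 5.32e-04). An estimated correlation gave the monocyte list an adjusted p of 0.182. The median was 0.40 without amiodarone replicate 1, 0.42 without amiodarone replicate 2 and 0.17 without a filter on low values, with the list still called. Among those that rose were the integrin gene ITGAX (2.29-fold), the transcription factor gene EGR2 (4.25-fold) and the costimulatory receptor gene CD86 (2.15-fold). The list has 25 members, and the rest were under the filter, which can favour genes that rise here as well.

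Inflammation genes rose. 22 of 23 tested members were higher, 12 by at least 2-fold, and 1 was lower, with a median log2 fold change of 1.05 (camera, adjusted p = 1.12e-11). This call held with an estimated correlation (adjusted p = 0.0193). Beside the chemokine genes, NFKBIA, which encodes an inhibitor of NF-kB and is also its target, rose 2.57-fold (90.8 ± 1.42 to 234 ± 0.538). Of 17 immediate early genes 10 rose and 4 fell, with a median of 0.24 (camera, adjusted p = 0.0295). That call ended without a filter on low values (adjusted p = 0.0556), and its adjusted p was 0.2 with an estimated correlation. KLF6 rose 2.04-fold and ZFP36, which encodes an mRNA decay factor, 1.56-fold. The interferon response list was not called (camera, adjusted p = 0.0808), with 11 of 22 higher (10 adjusted over the list alone), 4 lower and a median of 0.15, which was 0.04 at a minimum value of 5. IFIH1, a sensor of double-stranded RNA, rose 1.61-fold and RSAD2 from 0.737 ± 0.123 to 2.00 ± 0.07. RSAD2 passed the filter only through the amiodarone libraries, which favours a rise. HERC5 (6.54 ± 0.355 to 3.89 ± 0.155) and BST2 (82.2 ± 0.886 to 65.4 ± 2.89) fell.

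Glycolytic and nuclear-encoded mitochondrial genes were mostly lower. In the glycolysis and hypoxia list 24 of 31 fell and 5 rose, with a median log2 fold change of -0.68 (camera, adjusted p = 2.89e-04). The glycolysis list had an adjusted p of 0.0644 with an estimated correlation. The lactate dehydrogenase gene LDHA fell from 469 ± 7.03 to 138 ± 2.53, TPI1 from 548 ± 5.13 to 254 ± 1.99, ALDOC from 148 ± 0.94 to 66.4 ± 0.868 and PGK1 from 374 ± 8.48 to 182 ± 0.991. Complex I genes fell in 25 of 37 and rose in 3, with a median of -0.21 (camera, adjusted p = 0.0198). That call ended under a minimum value of 5 and under 2 of the scalings, and its adjusted p was 0.2 with an estimated correlation. NDUFS3 fell from 96.3 ± 3.3 to 65.3 ± 1.99 and NDUFA12 from 101 ± 3.79 to 73.0 ± 0.439, while NDUFV3 rose 1.85-fold. Genes of complexes II to V fell in 29 of 39 and rose in 2, with a median of -0.20 (camera, adjusted p = 0.00372). With an estimated correlation this list had an adjusted p of 0.2, and scaling by the median of ratios gave a median of -0.12. The ATP synthase genes ATP5MC1 (183 ± 3.89 to 87.2 ± 2.0) and ATP5F1B (411 ± 4.66 to 288 ± 4.45) fell, and ATP5F1E, with 23.2% of its exonic bases opposite TUBB1, rose 1.38-fold.

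Genes of mitochondrial biogenesis and proteostasis fell in 17 of 24 and rose in 4 (5 adjusted over the list alone), with a median of -0.44 (camera, adjusted p = 0.00649). Its adjusted p was 0.105 with an estimated correlation. The mitochondrial helicase gene TWNK fell from 17.6 ± 0.474 to 7.70 ± 0.127 and the import pore gene TOMM40 from 103 ± 3.47 to 57.2 ± 1.28. The chaperonin genes HSPD1 and HSPE1 fell from 292 ± 6.21 to 187 ± 1.21 and from 135 ± 7.06 to 54.2 ± 3.84. HSPE1 shares 18.6% of its exonic bases with HSPE1-MOB4 on the same strand and 16.4% with HSPD1 on the opposite strand. In fatty acid oxidation 14 of 20 fell, including HADH (25.3 ± 0.344 to 13.4 ± 0.462), ECI1 and HADHA. 5 rose, including PLIN2, a lipid droplet coat gene (2.35-fold), and the list was not called (median -0.27, camera, adjusted p = 0.127). The 13 mitochondrially encoded genes of a further list had no row in the table used here.

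Apoptosis genes went both ways, with 14 of 34 higher and 12 lower. The list was not called (camera, adjusted p = 0.237), with a median of 0 (-0.03 to 0.02 with 1 library left out), a mean of 0.12 and a test in the upward direction. The pro-apoptotic gene BBC3, which encodes PUMA, rose 3.43-fold. The anti-apoptotic genes BCL2A1 (63.0 ± 0.592 to 180 ± 2.05) and BIRC3 (4.88-fold) rose as well, while BIRC5, which encodes survivin and peaks in G2/M, fell from 17.8 ± 0.415 to 6.26 ± 0.312. In the list of p53 targets, in a line known to lack p53, 13 of 22 rose and 7 fell, with a median of 0.33 (camera, adjusted p = 0.0477). Its adjusted p was 0.2 with an estimated correlation. The cyclin-dependent kinase inhibitor gene CDKN1A rose 2.85-fold and BTG2 2.21-fold, and AEN fell from 9.56 ± 0.39 to 4.53 ± 0.172. This call was lost under 10 of the alternatives, among them leaving out control replicate 1 (adjusted p = 0.0583) or control replicate 2 (adjusted p = 0.051) and the replicate block (adjusted p = 0.0537).

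Of the known targets of amiodarone, 4 passed the filter, too few for a list test. The thyroid hormone receptor gene THRA fell (16.4 ± 0.986 to 10.5 ± 0.426), and the potassium channel gene KCNQ1 rose at a low level (0.327 ± 0.012 to 1.26 ± 0.046). KCNQ1 passed the filter only through the amiodarone libraries, which favours a rise. KCNJ11 rose from 1.12 ± 0.071 to 1.55 ± 0.413 (limma, adjusted p = 0.0464). That call ended without control replicate 1, 2 or 3 (adjusted p = 0.114, 0.0939 and 0.0602) or amiodarone replicate 2 (adjusted p = 0.202; log2 fold change 0.12, from 0.25), without a filter and with scaling to equal sums.

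Markers of other cell types also had too few tested members for a list test. Of 4 tested T and NK cell genes 3 rose, NKG7, a cytotoxic granule gene (126 ± 2.57 to 175 ± 4.73), KLRD1 (1.58-fold) and CD3G (0.72 ± 0.177 to 2.33 ± 0.261). Of 3 B cell genes CD22 rose (0.57 ± 0.087 to 4.05 ± 0.327), CD79A fell (11 ± 0.427 to 9.26 ± 0.384) and CD79B rose 1.15-fold, a call that ended with scaling to equal sums (adjusted p = 0.0855). CD79B shares 22.6% of its exonic bases with another annotated gene on the same strand. CD3G and CD22 passed the filter only through the amiodarone libraries, which favours a rise. EPOR (6.45 ± 0.062 to 4.82 ± 0.486) and ITGA2B (2.12 ± 0.17 to 1.51 ± 0.24), the 2 tested erythroid and megakaryocytic genes, fell. The epithelial gene KRT18 fell from 1.06 ± 0.06 to 0.617 ± 0.238, and the other tested epithelial gene was not called. PECAM1, the 1 tested fibroblast and endothelial gene, had values of 15.2 ± 0.225 and 15.2 ± 0.962 (limma, adjusted p = 0.89).

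**Figure D3:**
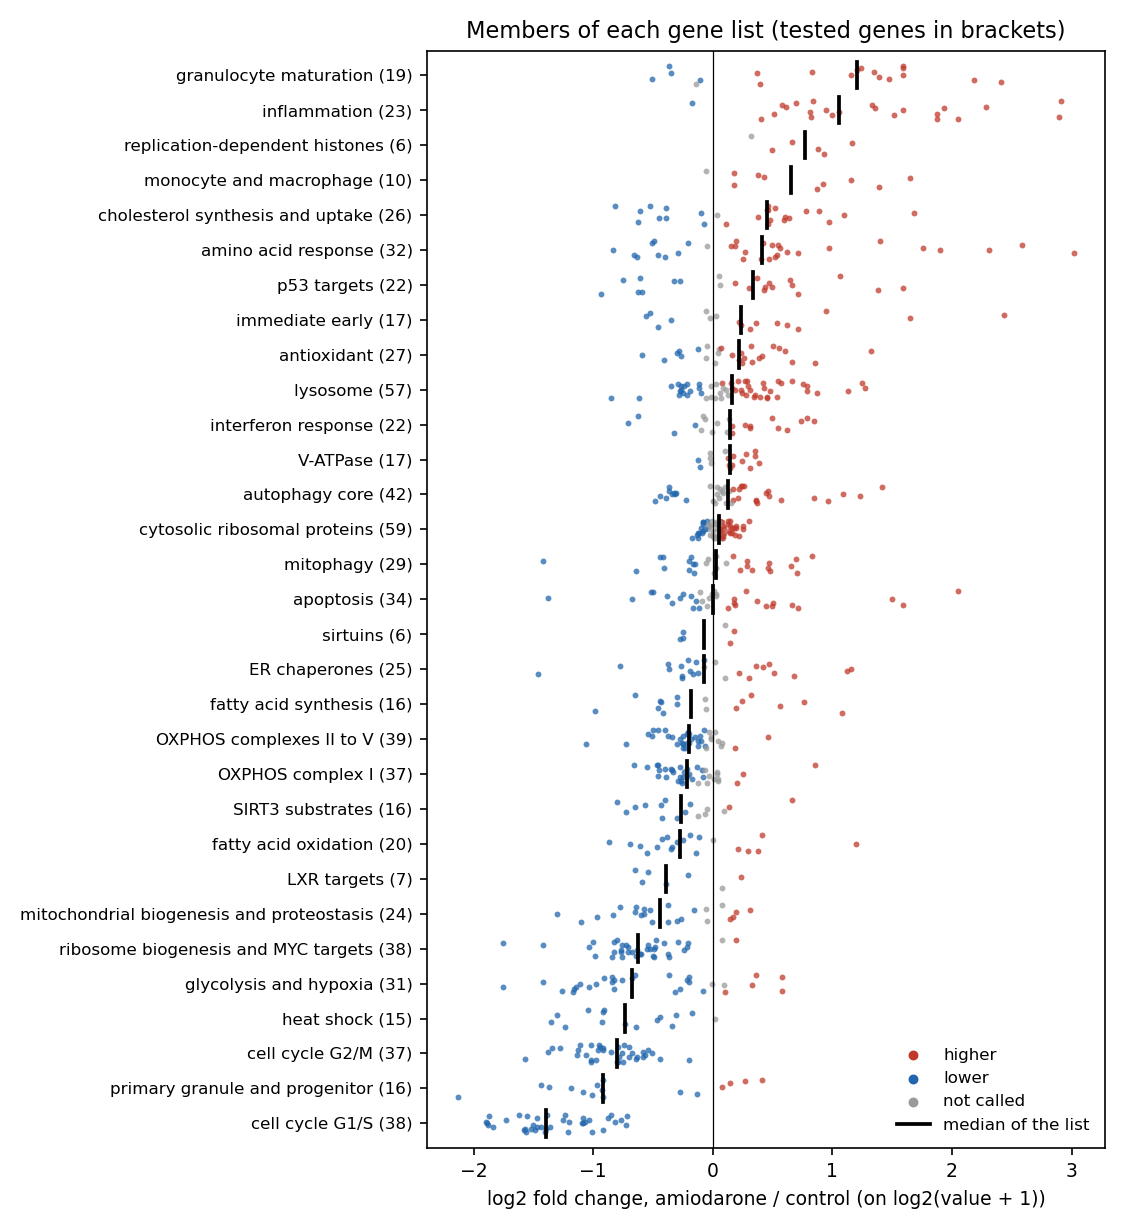
Log2 fold changes (amiodarone over control, on log2(value + 1)) of the tested members of the 31 gene lists with at least 5 of them, sorted by their medians; each point is a gene, red where higher, blue where lower and grey where not called, and black bars are medians. The medians run from -1.39 for G1/S genes to 1.2 for granulocyte maturation genes, whose median is 0.34 without a filter on low values. That of the cytosolic ribosomal proteins, 0.05, turns to -0.04 when libraries are scaled to equal sums, and other medians also depend on the filter or scaling.

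Of the 31 lists tested with camera at a preset correlation of 0.01, 23 were called, 13 higher and 10 lower. 3 of them held with an estimated correlation, those of G1/S genes, ribosome biogenesis and MYC targets, and inflammation. For each called list except the ribosomal proteins, the estimated correlation gave the highest adjusted p of all alternatives. Counts of members adjusted over the list alone equalled those over all genes tested, except in the 4 lists where both are given.

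A few genes took more of the summed values after amiodarone. The 50 most abundant genes held 28.9% ± 0.138 in controls and 35.6% ± 0.102 after amiodarone, while the ribosomal protein list held 24.1% ± 0.184 and 23.3% ± 0.152. Each difference had p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 libraries can give, and 0.1 after adjustment over 4 shares. The share of the MTRNR2L genes rose by 8.31 points, more than that of the 50 most abundant genes (6.73 points).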

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

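The 3 scalings, the robust variances and the test against a 1.5-fold change were chosen after the values were seen. Alternatives that need counts (a second count model, voom weights, trimmed-mean and size-factor scalings, a count test against a fold) were not run. The number of called genes ranged from 6941 (minimum value 5, with 8470 genes tested) to 10264 (no filter, 17910 tested), and from 8346 to 8487 when any 1 library was left out. The number past 2-fold moved to 1129 with a pseudocount of 0.1 (602 higher, 527 lower), which understates low genes less. The test against 1.5-fold counts another quantity, and 1352 genes passed it. Median-of-ratios scaling raised the median log2 fold change of all genes from -0.06 to 0.01 and equal sums lowered it to -0.15. The log2 fold change of SIRT3 stayed called and negative in all alternatives, from -0.33 (equal sums) to -0.18 (median of ratios). Of 2469 alternative fits of 157 named genes, none reversed a call and 8 lost it (6 of KCNJ11, 1 each of CD79B and SIRT2). Some genes were not tested in every alternative: 147 were at a minimum value of 5, and 150 without amiodarone replicate 1 or 3. Genes that reach a value of 1 only after amiodarone, such as GDF15, dropped out when an amiodarone library was left out.

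Replicate numbers gave no sign of pairing the libraries. Deviations from the group means correlated at -0.155, -0.018 and -0.023 between libraries of the same number, and no library correlated best with its own number. The check cannot exclude pairing, since replicate variance was only 1.62 (controls) and 1.92 (amiodarone) times that of counting. With the number as a block 8770 genes were called, 8706 of them shared with the 8959 of the unblocked test, and 589 passed 2-fold; the p53 target list lost its call (median 0.33, adjusted p = 0.0537), and no other list did.

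With an estimated correlation 20 lists lost the call at unchanged medians, given here with the adjusted p: amino acid response (0.41, 0.0735), antioxidant (0.22, 0.2), autophagy core (0.12, 0.108), G2/M (-0.80, 0.0646), cholesterol synthesis and uptake (0.46, 0.242), cytosolic ribosomal proteins (0.054, 0.537), glycolysis and hypoxia (-0.68, 0.0644), granulocyte maturation (1.2, 0.108), heat shock (-0.73, 0.0644), immediate early (0.24, 0.2), lysosome (0.16, 0.105), mitochondrial biogenesis (-0.44, 0.105), monocyte and macrophage (0.65, 0.182), complex I (-0.21, 0.2), complexes II to V (-0.20, 0.2), p53 targets (0.33, 0.2), primary granule (-0.92, 0.105), histones (0.77, 0.213), SIRT3 substrates (-0.26, 0.264) and V-ATPase (0.14, 0.182). For some of these 20 lists the estimate lay below the preset 0.01, so a higher correlation did not end their calls. They were the lists of heat shock (-0.0499), primary granule, mitochondrial biogenesis, glycolysis, autophagy core, amino acid response, p53 target and lysosomal genes. The rest of the 20 had estimates above 0.01, up to 0.269 for histones. With an estimated correlation camera also has only the 4 residual degrees of freedom, which by itself raises p. The adjusted p of the G1/S list, with an estimate of 0.0026, went from 3.09e-14 to 0.0193 in this way. For the lists with estimates above 0.01, these 2 differences were not separated. With fry, which does not compare a list with other genes, 6 more were called: apoptosis (median 0), ER chaperones (-0.076), fatty acid oxidation (-0.27), fatty acid synthesis (-0.18), interferon response (0.15) and LXR targets (-0.40). The ribosomal protein list turned to -0.037 with equal sums (adjusted p = 0.974) and lost its call at 0.054 without a filter, as did immediate early genes at 0.24 and p53 targets at 0.19. At a minimum value of 5 the call was lost by complex I (-0.21), p53 targets (0.42) and SIRT3 substrates (-0.26). After median-of-ratios and upper-quartile scaling it was lost by complex I (-0.13 and -0.14), p53 targets (0.40 and 0.40) and SIRT3 substrates (-0.18 and -0.19), and without the 50 most abundant genes by p53 targets (0.38) and SIRT3 substrates (-0.21). With members of a mean of at least 5 p53 targets lost it (0.42). Leaving out 1 library, the p53 median ranged from 0.31 to 0.37, with the call lost without control replicate 1 or 2, and that of the SIRT3 substrates from -0.28 to -0.25, lost without amiodarone replicate 1. Apart from the fewer genes tested at a minimum value of 5 and the fewer degrees of freedom with an estimated correlation, the cause was not tested. Depth limits genes near a value of 1 to about 52 to 61 reads.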

Other observations

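The tests of a few abundant genes for G1/S genes and of monocytes, the families of genes by name and all genes outside the lists here were chosen after the values were seen; the other tests of explanations were set before their results. Several abundant myeloid transcripts outside the lists changed. PRG2, the eosinophil major basic protein gene, fell from 861 ± 6.07 to 297 ± 4.47 (SD, n = 3 per group; limma, adjusted p = 1.07e-12). AIF1, a macrophage-associated calcium-binding protein gene, fell from 347 ± 10.9 to 215 ± 3.76. FCER1G, the common gamma chain of Fc receptors, rose 2.61-fold (222 ± 8.42 to 581 ± 2.93) and TYROBP, a related adaptor of other receptors, 1.77-fold. NAMPT, the rate-limiting enzyme of NAD salvage, rose 3.90-fold (28.5 ± 0.866 to 111 ± 2.84; adjusted p = 4.56e-12). Each of these genes was separated between groups in 3 of 3 libraries.

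All 73 families of at least 15 tested genes whose symbols share the letters before the first digit were tested with camera. 4 were called and none with an estimated correlation: histone genes named HIST rose in 16 of 18 (median log2 fold change 0.67; adjusted p = 9.59e-04), nucleoporin genes named NUP fell in 18 of 20 (median -0.44; adjusted p = 9.59e-04), RNA polymerase subunit genes named POLR fell in 23 of 30 and rose in 3 (median -0.31; adjusted p = 0.0387), and genes of the large mitochondrial ribosomal subunit named MRPL fell in 32 of 49 and rose in 5 (median -0.28; adjusted p = 0.0392). With an estimated correlation the adjusted p was 0.616 for each of the 4. Some of the HIST genes passed the filter only through the amiodarone libraries, which favours a rise.

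The MTRNR2L genes, nuclear copies of the mitochondrial 16S ribosomal RNA gene MT-RNR2, took 1.72% ± 0.034 of the summed values in controls and 10.0% ± 0.119 after amiodarone (exact permutation p = 0.1, the smallest possible). All 9 tested copies were higher, by 4.35-fold to 14.2-fold; MTRNR2L2 rose from 4302 ± 92.6 to 24643 ± 379, MTRNR2L8 on chromosome 11 from 2302 ± 46.2 to 14298 ± 265 and MTRNR2L1 on chromosome 17 from 860 ± 16.5 to 6488 ± 101. Scaling by the median of ratios left the median log2 fold change of the copies at 2.78, but it moved the median of all genes only from -0.06 to 0.01 and so decides nothing about them. A candidate explanation for where their reads come from is that the mitochondrial rRNA itself was counted on its nuclear copies: over the 8 copies with a transcript of at least 500 bases, which are 78.2% to 93.0% identical to MT-RNR2, those with higher identity had higher values after amiodarone (Spearman rho = 0.857 across genes, which are not independent replicates; exact permutation p = 0.0107, two-sided). The control values gave the same rho of 0.857, and over the 7 of these copies with a ratio of means rho for that ratio was 0.143. The ranking thus bears on the source of the reads in both groups and not on the rise. Whether amiodarone changed the amount of that rRNA, its polyadenylation or its carry-over into the libraries stays open, since the table used here has no mitochondrially encoded gene.

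The lower G1/S genes were weighed against 2 technical explanations. A few abundant genes taking more of the reads would lower all genes alike, yet the median log2 fold change of all tested genes was -0.06. Left without the 50 most abundant genes and rescaled, the list still had a median log2 fold change of -1.34. After removal of the trend of change on gene length its median was -1.39. Neither outcome was open. Leaving out those genes moved the median of all genes only from -0.061 to -0.017, and the length trend spanned -0.056 to 0.227 around that median. What the values show is that both shifts were too small to be the whole cause of the lower G1/S genes. A lower share of cycling cells after amiodarone may be the biological side of this pattern; it was not measured here.

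The higher inflammation genes kept a median of 1.055 after removal of the length trend. That trend spanned only -0.056 to 0.227 around the median of all genes, so its removal could not have taken the rise away. Monocytes carried in from elsewhere are argued against, since they would bring their abundant transcripts: the mean values after amiodarone were 0.013 for VCAN, 0.793 for CD14, 0.283 for HLA-DPA1 and 0.39 for HLA-DPB1, while CXCL8 reached 1786. A response of the HL-60 cells themselves to the drug remains an open hypothesis, and a difference between cultures handled apart from each other could not be separated from it in this design.

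The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the most calls: it gave 8959 genes, 589 genes past 2-fold and 23 lists, where the highest of the other splits gave 0, 0 and 17. The other splits leave part of the treatment difference between their groups, and camera with the preset correlation called lists in each of them.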
